A study of Mus musculus with 15 samples.

How the data were processed

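Messenger RNA was measured on 15 Affymetrix Mouse Genome 430 2.0 arrays, 1 array per RNA sample of primary mouse hepatocytes. The labels give 5 adenovirus groups of 3 arrays, and the series text states that 3 experiments were conducted independently. The hepatocytes carried EGFP, wild-type IRE1a or S724A IRE1a for 48 hours, or a control hairpin or a hairpin against IRE1a for 72 hours followed by 4 hours of glucagon. Per the labels, the authors processed the arrays with GCRMA, which corrects the background by probe sequence, normalises by quantiles across arrays and summarises each probe set by median polish; its version is not given in the sources used here. The deposited values are log2 signals, 1 per probe set and array. The scale was read from the values, since the labels do not state it: the array medians lay between 5.69 and 5.83, and the values showed no centring per gene.

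The table holds 45101 probe sets. After 64 control probe sets were left out, 34945 probe sets with 1 gene symbol in the platform's annotation were used to name genes; 932 with several symbols and 9160 with none were tested apart. Of the probe sets with 1 symbol, 34741 had a gene number that matched the reference gene table of assembly GRCm38.p6. Where a gene had several probe sets, the one with the highest mean over all 15 arrays stood for it, which gave 18193 genes. A gene was tested when its value was 4 or more in at least 3 of the 15 arrays, which left 16294 genes. Signals near background limit what these arrays can show, and the number of arrays limits the precision: the 95% confidence interval of a change had a median half-width of 0.30 on the log2 scale.

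The comparisons were made in R 4.3.3 with limma 3.58.1. A linear model of 5 groups was fitted to all 15 arrays at once (lmFit, then eBayes, 10 residual degrees of freedom), and 4 contrasts were taken: wild-type IRE1a minus EGFP, S724A IRE1a minus EGFP, wild-type minus S724A IRE1a, and IRE1a hairpin minus control hairpin, both with glucagon. No contrast joined the 48-hour and the 72-hour groups, which differ in virus, time and glucagon. All p-values for genes are from limma's moderated test, two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Errors of changes are limma's standard errors, and errors of group values are standard deviations over 3 arrays.

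Gene lists for hepatocyte functions, stress responses and other cell types of the liver were fixed before the data were examined, and 36 of them had at least 5 tested members. Each was tested against all other genes with limma's camera, with the correlation between genes preset at 0.01 and again with the correlation estimated per list, with adjustment over the 36 lists of a comparison. Members past the threshold were counted over all genes tested and also adjusted over the list alone. A further list of sex-linked transcripts served only as a check of the samples. The genes named in the text were chosen by a rule also fixed before the data were examined: Ern1; a core of G6pc, Pck1, Ppargc1a, Tat, Xbp1, Hspa5, Dnajb9, Ddit3, Atf4 and Fgf21; the 6 largest rises and 6 largest falls past the threshold whose 3 arrays of one group all lay above the 3 of the other; and up to 4 members, by smallest p, of each list that shifted or had 3 or more members past the threshold. Where no gene passed, the 4 with the smallest p in each direction were named as values. Genes named outside this rule are said to be so.

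Effects were compared across genes by Pearson and Spearman correlation, with a null from relabelling the arrays within each arm, or from 100 simulations of unchanged groups that share the EGFP arrays. Both treat arrays as independent, so residuals of same-number arrays and the 64 swaps within same-number pairs were added after the data were seen. The gene and list tests were tried on simulated data built from the gene means and spreads of these arrays. The gene test recovered between 79.2% and 89.7% of genes changed by 1 on the log2 scale. Of genes changed by 0.5 it recovered between 24.7% and 43.8%, with at most 10 false calls in a comparison. Each simulation changed 53 to 82 genes per size of change and drew noise independently for each gene and array. It thus left out the pairing of same-number arrays, and its false calls do not carry over to larger counts of genes.

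The replicate numbers are paired with experiments nowhere in the labels. Within an arm, all 12 pairs of arrays with the same number in different groups had correlated residuals (r from 0.20 to 0.69), while across the arms 4 of 18 exceeded 0.1. The arrays of an arm were therefore also compared with the replicate number as a block within each arm, an alternative added after the data were seen. The alternatives fixed beforehand were quantile normalisation or median centring of the deposited values, no filter or a stricter filter of 6 on dim signals, a floor of 4, a fit of the 6 arrays of a comparison alone, trended and robust variances, array weights, the mean of a gene's probe sets, each probe set on its own, the replicate number as a block over all arrays, and leaving out each array in turn. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

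Among the named genes past the threshold, 79 cases had several probe sets: in 68 all probe sets had the same sign, and in 0 did limma place another probe set past the threshold in the opposite direction. Of 30 spike-in probe sets, 0 passed the threshold of limma in any comparison, and their largest change was 0.32 on the log2 scale. No pair of arrays was identical, and the highest correlation between 2 arrays was 0.996.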

Results

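The data are 15 arrays of primary mouse hepatocytes in 5 groups of 3 arrays each. IRE1a, the product of Ern1, is a stress sensor in the membrane of the endoplasmic reticulum (ER). Its RNase splices the messenger RNA of the transcription factor XBP1. Adenoviruses carried the control protein EGFP, wild-type IRE1a or S724A IRE1a, in which a serine is replaced by alanine, for 48 hours. In a separate arm they carried a control hairpin or a hairpin against IRE1a for 72 hours, followed by 4 hours with glucagon, the hormone that raises glucose output by the liver. Array medians lay between 5.69 and 5.83 on the log2 scale, and between 79.0% and 81.4% of the probe sets reached a signal of 4. Changes below are differences of log2 signals ± SE with n = 3 arrays per group. Each gene named as risen or fallen had all 3 arrays of one group above all 3 of the other. Counts of genes that rose or fell rest on the threshold and the direction alone.

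Wild-type IRE1a was compared with EGFP to show what a virus carrying IRE1a changes in hepatocytes. Bhlha15, a transcription factor of secretory cells, rose by 3.65 ± 0.25 (12.6-fold, adjusted p = 7.75e-07). Fkbp11, an ER prolyl isomerase, rose by 3.26 ± 0.11 (9.56-fold, adjusted p = 7.17e-10), Arfgef3 by 3.44 ± 0.17 and Nucb2, a calcium-binding protein, by 2.76 ± 0.23. With the mean of their probe sets Bhlha15 and Fkbp11 rose by 2.27 and 1.17, and 1 of 2 and 1 of 3 probe sets passed. Fam107a, an actin-binding protein, rose by 3.58 ± 0.90 (adjusted p = 0.0247), a call lost without EGFP replicate 2, EGFP replicate 3, wild-type replicate 1 or wild-type replicate 3 and with trended variances (adjusted p up to 0.119). Esco2, a cohesin acetyltransferase, rose by 2.52 ± 0.58, a call lost without EGFP replicate 1, EGFP replicate 2 or wild-type replicate 3 (adjusted p up to 0.0791). The falls were led by the heat shock gene Hspa1a at -3.88 ± 0.36 (14.7-fold lower, adjusted p = 1.03e-05). The carboxylesterase Ces1c followed at -2.93 ± 0.26, the receptor gene Ager at -2.79 ± 0.17 and the collagen-modifying enzyme Plod2 at -2.43 ± 0.35. The fall of Ager rested on 1 of 2 probe sets, the other differing by -0.01, and was -1.40 with their mean. Rgcc and Cyp2e1, a cytochrome P450, changed by -2.32 ± 0.39 and -2.27 ± 0.43.

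By list, 28 of the 31 tested genes of ER translocation and COPII transport rose with wild-type IRE1a (29 adjusted over the list alone). The list shifted upward in camera (adjusted p = 1.28e-35, and adjusted p = 0.0428 with an estimated correlation). Sec61b, a subunit of the translocation channel, rose by 2.15 ± 0.12, and Sec11c, of the signal peptidase, by 1.71 ± 0.11. Of 26 ER chaperones and folding enzymes, 16 rose (20 adjusted over the list alone), among them Manf by 2.30 ± 0.11, Hspa13 by 1.56 ± 0.11 and Pdia6 by 1.55 ± 0.12. The chaperones too shifted upward (adjusted p = 1.08e-20, and adjusted p = 0.0428 with an estimated correlation). Of 26 N-glycosylation genes, 15 rose and 1 fell (18 and 2 adjusted over the list alone). That list had adjusted p = 2.61e-10, but adjusted p = 0.193 with an estimated correlation. Ostc and Magt1, subunits of the oligosaccharyltransferase, rose by 2.10 ± 0.16 and 1.76 ± 0.13, and the gene that fell was Alg1 at -0.58 ± 0.10, named after its values were seen. Of 21 genes of ER-associated degradation, 11 rose (12 rose and 1 fell adjusted over the list alone), with Edem2 at 1.69 ± 0.15 and Herpud1 at 1.63 ± 0.17. This list had adjusted p = 7.43e-09, but adjusted p = 0.0519 with an estimated correlation. With the mean of their probe sets Sec11c, Pdia6 and Edem2 rose by 1.01, 0.99 and 0.92, and 1 of 2 probe sets of each passed.

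In the fixed core, Dnajb9 rose by 1.34 ± 0.20, Xbp1 by 0.63 ± 0.11 and Hspa5, the chaperone BiP, by 0.56 ± 0.11 with wild-type IRE1a. The PERK, ATF4 and CHOP target genes did not shift (camera adjusted p = 0.768): of 27 tested, limma placed 0 among the rises and 1, Slc7a11, among the falls (2 rose and 1 fell adjusted over the list alone). Ddit3 and Atf4 differed by 0.19 ± 0.19 and 0.09 ± 0.12 (adjusted p = 0.617 and 0.722).

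**Figure D1:**
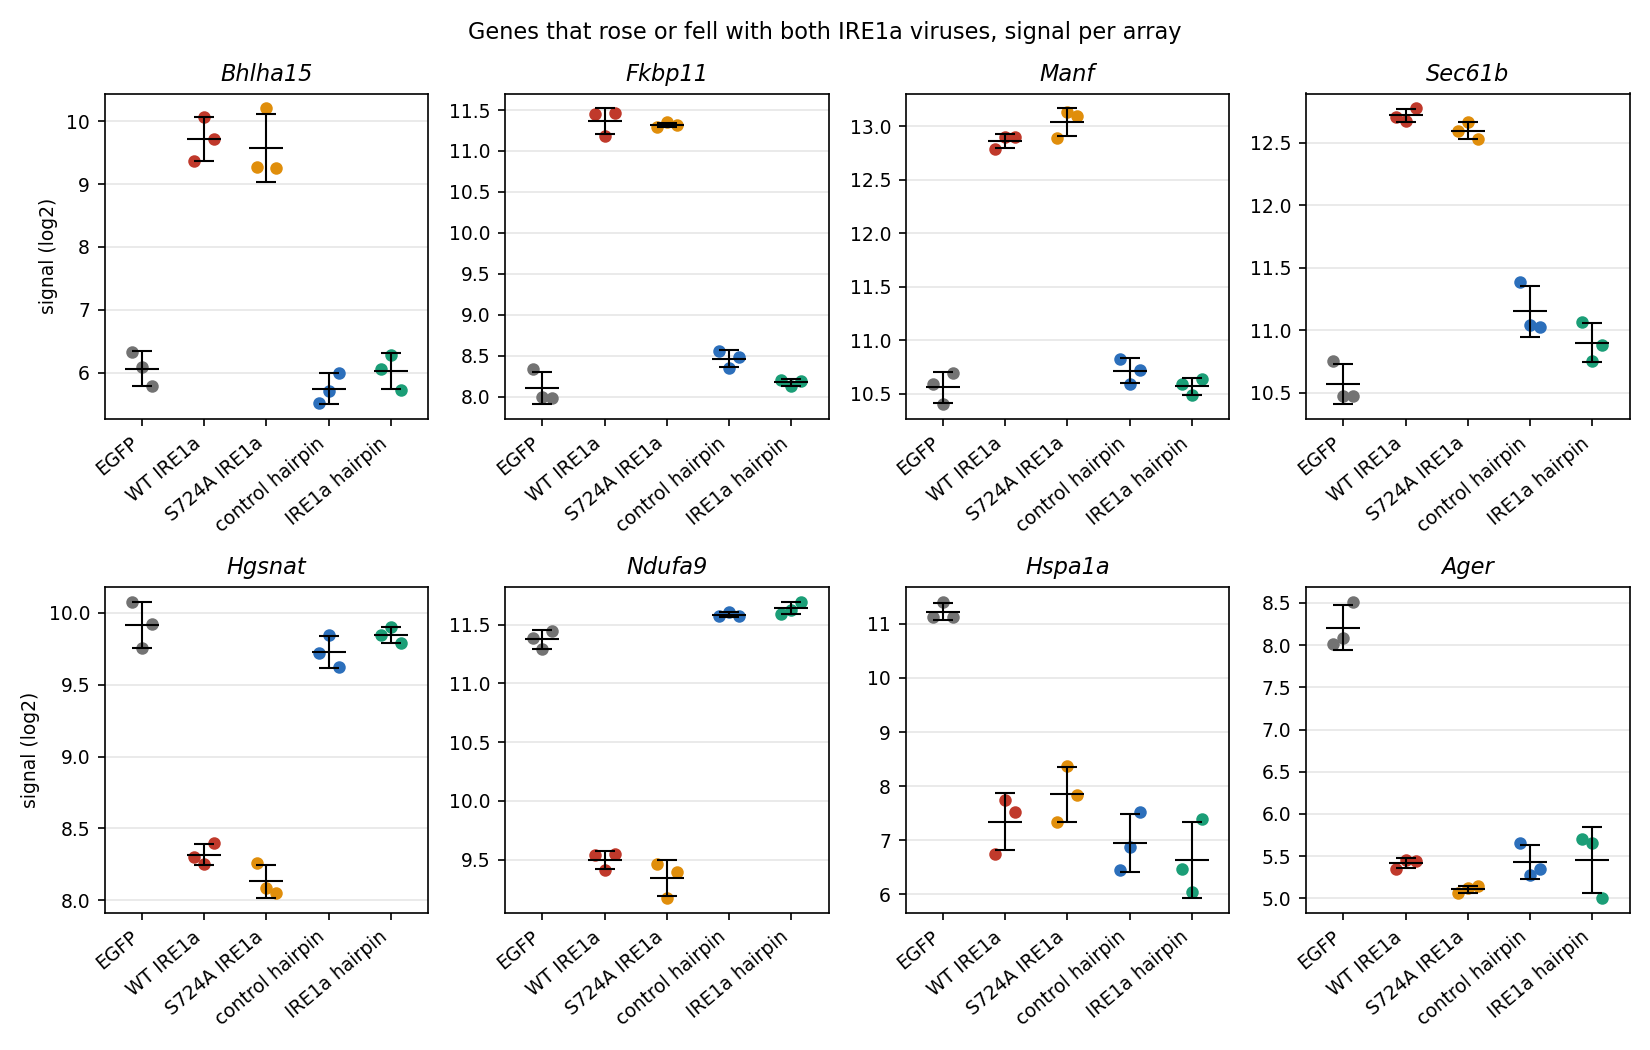
Signal per array (log2, vertical axes that differ between panels and do not start at 0) of 8 named genes in the 5 groups; dots are arrays, horizontal bars are means and whiskers are SDs (n = 3), and both hairpin groups received glucagon. Bhlha15, Fkbp11, Manf and Sec61b lie higher with both IRE1a viruses than in all other arrays, while Hspa1a and Ager are high in the EGFP arrays alone.

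Several lists were lower with wild-type IRE1a. Of 15 messages reported as substrates of decay by the IRE1 RNase, 4 fell (1 rose and 7 fell adjusted over the list alone). The substrate list had camera adjusted p = 0.00103, but adjusted p = 0.0691 with an estimated correlation. Hgsnat, a lysosomal acetyltransferase, changed by -1.60 ± 0.10, Tapbp by -0.89 ± 0.17, Cyp2e1 as given above and Rtn4 by -0.48 ± 0.12. The call of Rtn4 was lost without any 1 of EGFP replicates 1 and 2 and the 3 wild-type replicates and with the mean of its probe sets (adjusted p up to 0.0904). Among 20 NRF2 and antioxidant genes 5 fell (5 adjusted over the list alone). The NRF2 list had adjusted p = 0.000210, but adjusted p = 0.564 with an estimated correlation. Taldo1 changed by -1.57 ± 0.21, the cystine transporter Slc7a11 by -1.42 ± 0.24, Abcc4 by -1.33 ± 0.24 and Txnrd1 by -0.89 ± 0.12. The other was Tkt at -0.47 ± 0.11, named after its values were seen, whose call was lost without EGFP replicate 3 and with the mean of its probe sets (adjusted p up to 0.0557).

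Of 17 cytosolic heat shock genes 2 fell with wild-type IRE1a (2 adjusted over the list alone): Hspa1a, and Hspa1b by 2.10 ± 0.20. The heat shock list had adjusted p = 6.27e-05, but adjusted p = 0.166 with an estimated correlation. The signals of Hspa1a, Hspa1b and Ager were also low with the control hairpin, at 6.95 ± 0.54, 9.96 ± 0.13 and 5.43 ± 0.20 (SD). With EGFP they were 11.22 ± 0.16, 12.37 ± 0.18 and 8.21 ± 0.27. Of 29 plasma protein and hepatocyte identity genes, 1 rose and 3 fell (1 and 4 adjusted over the list alone). The plasma protein list had adjusted p = 0.0102, but adjusted p = 0.736 with an estimated correlation, and was lost without EGFP replicate 1 (adjusted p = 0.0790). The complement gene Hc changed by -1.86 ± 0.21, the protein C gene Proc by -0.96 ± 0.20 and prothrombin, F2, by -0.78 ± 0.14. Hnf4a rose by 0.74 ± 0.19, a call lost without EGFP replicate 2, wild-type replicate 2 or wild-type replicate 3 (adjusted p up to 0.126). Outside lists that shifted, the triglyceride enzyme Dgat2 changed by -1.74 ± 0.29, the complex I subunit Ndufa9 by -1.88 ± 0.09, and the lysosomal genes Lamp1 and Tpp1 by -1.17 ± 0.12 and -1.12 ± 0.19. Their lists had 0 rises and 3 falls (fatty acid and triglyceride synthesis), 1 and 3 (oxidative phosphorylation) and 1 and 4 (autophagy and lysosome). Wipi1, in the last of these, changed by 0.99 ± 0.16, or by 0.63 with the mean of its probe sets. Amino acid catabolism and urea cycle genes had 3 rises and 0 falls, xenobiotic metabolism and cholesterol synthesis genes 2 and 2 each, and bile acid genes 2 and 1.

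Of 28 cell cycle genes 7 rose with wild-type IRE1a (12 rose and 2 fell adjusted over the list alone). The cell cycle list had camera adjusted p = 0.0409, but adjusted p = 0.796 with an estimated correlation. This shift was lost without EGFP replicate 1, EGFP replicate 2, wild-type replicate 2 or wild-type replicate 3 and in 3 other settings (adjusted p up to 0.240). Aurkb rose by 1.81 ± 0.39, a call lost without EGFP replicate 2 (adjusted p = 0.0561). Fatty acid oxidation and PPARA target genes had a mean change of 0.42 (adjusted p = 0.00306, but adjusted p = 0.736 with an estimated correlation). Of these 25 genes 1 rose in limma (0 adjusted over the list alone): Hadhb by 0.45 ± 0.13. That call was lost in 5 settings and without any 1 of EGFP replicates 2 and 3 and the 3 wild-type replicates (adjusted p up to 0.208). Interferon response genes had a mean of 0.28 (adjusted p = 0.0123, but adjusted p = 0.736 with an estimated correlation). The interferon shift was lost without EGFP replicate 2 and with the stricter filter (adjusted p up to 0.114). Of these 30 genes 1 rose in limma (0 adjusted over the list alone): Psmb9 by 0.77 ± 0.20. Its call was lost without EGFP replicate 1, EGFP replicate 2, wild-type replicate 2 or wild-type replicate 3 (adjusted p up to 0.138).

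Gluconeogenesis genes did not shift with wild-type IRE1a (1 of 15 rose, adjusted p = 0.383). The gene that rose, Pck1, encodes a rate-limiting enzyme of the pathway and gained 1.03 ± 0.22 from a low signal of 5.36 ± 0.35 (SD). Its call was lost without EGFP replicate 2, without wild-type replicate 3 and with the mean of its probe sets (adjusted p up to 0.228). G6pc, Tat, Ppargc1a and Fgf21 differed by 0.57 ± 1.07, 0.47 ± 0.27, -0.32 ± 0.32 and 1.66 ± 0.51 (adjusted p = 0.818, 0.350, 0.612 and 0.0606). Fgf21 was higher in 3 of 3 same-number pairs and passed with the replicate number as a block within each arm and without EGFP replicate 3 (adjusted p = 0.000205 and 0.0299), and Tat passed with that block (adjusted p = 0.0168). Markers of macrophages, endothelial cells, stellate cells, cholangiocytes, lymphocytes and neutrophils, and erythroid cells did not shift (adjusted p = 0.444, 0.720, 0.316, 0.383, 0.297 and 0.768).

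In total 828 genes rose and 422 fell with wild-type IRE1a among 16294 tested, and 161 and 86 of them by at least 2-fold. The groups did not overlap in 4344 genes (26.7%), against 10% by chance if the arrays were independent, which same-number arrays were not. Of 36 lists, 7 shifted up and 4 down, and 2 held with an estimated correlation. With the replicate number as a block within each arm 2539 genes passed, 1249 of them shared with the unblocked count, and without EGFP replicate 2 the count was 715 (409 rose and 306 fell). Without wild-type replicate 3 the rises numbered 467 and the falls 376. The share of rising genes, 66.2%, thus depended on single arrays, and on the scaling: it was 55.3% after quantile normalisation and 49.6% after median centring.

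S724A IRE1a was compared with EGFP to ask the same of the altered protein. The rises were led by Arfgef3 at 3.68 ± 0.17 (12.8-fold, adjusted p = 1.05e-08), Bhlha15 at 3.51 ± 0.25, Fkbp11 at 3.21 ± 0.11 and Nucb2 at 3.07 ± 0.23. The ER chaperone cofactor Sdf2l1 rose by 2.62 ± 0.26 and Manf by 2.48 ± 0.11. Hspa1a was again lowest at -3.37 ± 0.36 (10.4-fold lower, adjusted p = 4.14e-05), followed by Ager at -3.10 ± 0.17 and Ces1c at -2.75 ± 0.26. Ndufa9 changed by -2.03 ± 0.09, the ER-phagy receptor gene Retreg3 by -2.02 ± 0.33 and Plod2 by -1.89 ± 0.35. With the mean of their probe sets Bhlha15, Fkbp11, Ager and Retreg3 changed by 2.21, 1.10, -1.54 and -0.98. The chemokine gene Cxcl2 was higher by 3.11 ± 0.87 (adjusted p = 0.0493). That call was lost without any 1 of the 3 EGFP arrays, S724A replicate 2 or S724A replicate 3 and in 6 other settings (adjusted p up to 0.187).

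Of the ER lists, 26 of 31 translocation and COPII genes, 21 of 26 chaperones and 10 of 21 genes of ER-associated degradation rose with S724A IRE1a. The counts were 28 rises and 1 fall, 22 rises, and 14 rises adjusted over the list alone. These 3 lists shifted in camera (adjusted p = 3.59e-35, 5.07e-31 and 1.26e-13, and adjusted p = 0.0170 with an estimated correlation for each). Pdia6 rose by 2.01 ± 0.12, Sec61b by 2.03 ± 0.12, Lman1, a cargo receptor of ER exit, by 1.45 ± 0.11, Edem2 by 1.70 ± 0.15, and Hspa5 by 0.83 ± 0.11. With the mean of their probe sets Pdia6 and Edem2 rose by 1.09 and 0.96, and 1 of 2 probe sets of each passed. Of 26 N-glycosylation genes 18 rose, with Ostc at 2.03 ± 0.16, and 1 fell (20 and 1 adjusted over the list alone), again Alg1 at -0.51 ± 0.10. Here camera gave adjusted p = 6.81e-18, but adjusted p = 0.0709 with an estimated correlation. Xbp1 rose by 0.52 ± 0.11, a call lost without EGFP replicate 2 or S724A replicate 2 (adjusted p up to 0.0737). The PERK, ATF4 and CHOP target genes did not shift (adjusted p = 0.336). Of these 27 limma placed 0 among the rises and 1 among the falls (1 rose and 1 fell adjusted over the list alone): Vldlr at -1.64 ± 0.43, named after its values were seen. Its call was lost without EGFP replicate 2, EGFP replicate 3 or any 1 of the 3 S724A arrays, with trended variances and with the mean of its probe sets (adjusted p up to 0.125).

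**Figure D2:**
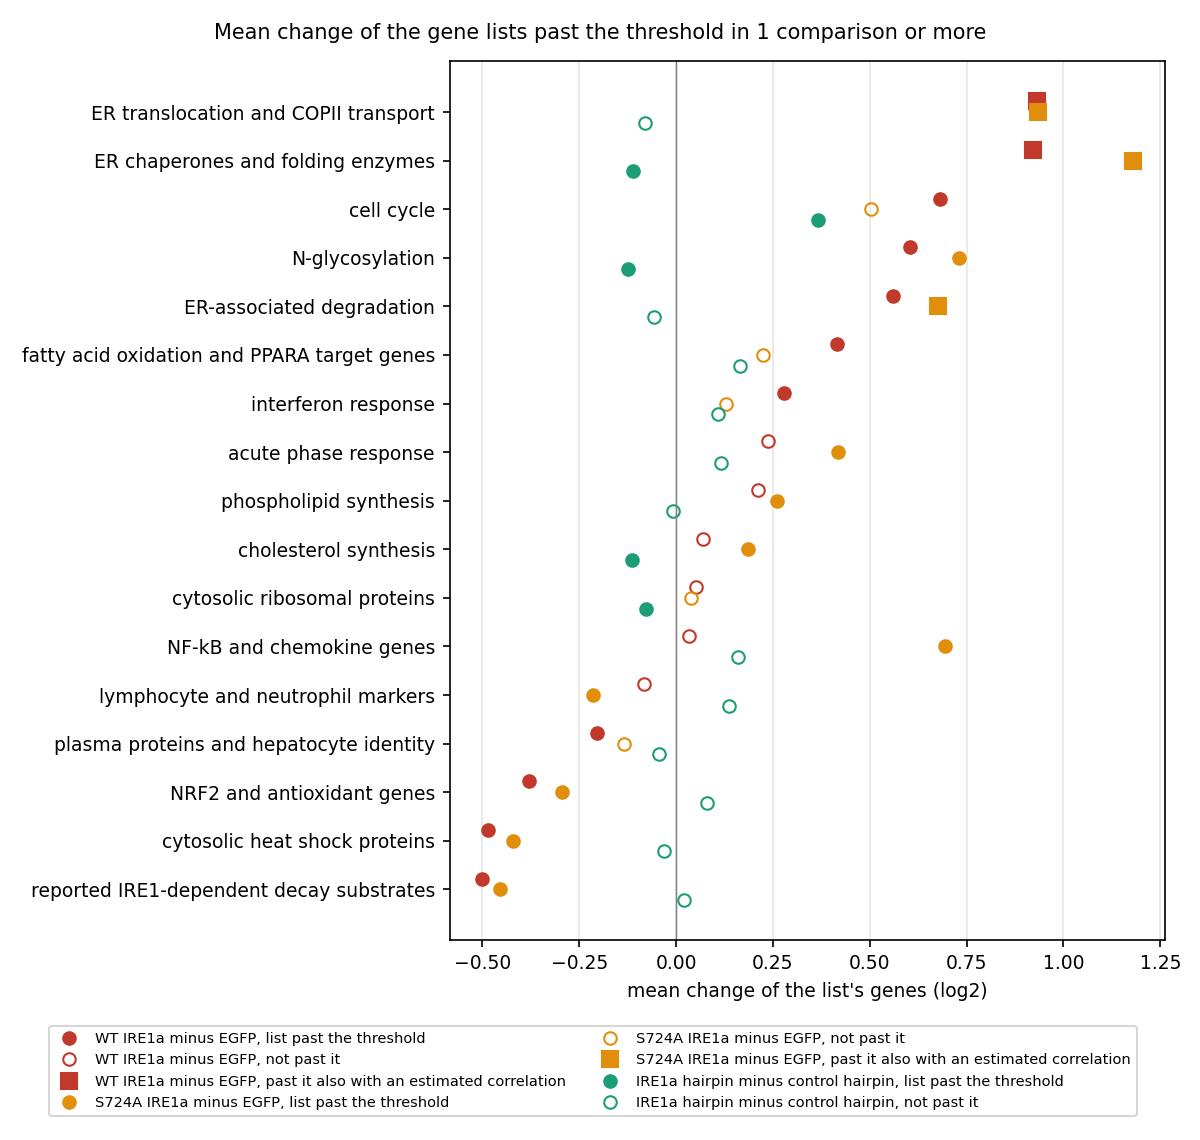
Mean log2 change (horizontal axis) of the genes of each list that passed the threshold in 1 or more of the 3 comparisons drawn; filled circles passed camera's threshold, squares passed it also with an estimated correlation, and open circles did not pass. The ER lists lie far to the right with both IRE1a viruses, at means of 0.56 to 1.18, and at or below 0 with the hairpin against IRE1a.

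Of the reported decay substrates, 4 of 15 fell with S724A IRE1a (5 adjusted over the list alone). The list had adjusted p = 0.00228, but adjusted p = 0.0709 with an estimated correlation. Hgsnat changed by -1.78 ± 0.10. Cyp2e1 at -1.76 ± 0.43 was also past the threshold, a call lost without any 1 of the 3 EGFP arrays, S724A replicate 2 or S724A replicate 3 and with trended variances (adjusted p up to 0.0998). Tapbp at -0.71 ± 0.17 was lost without EGFP replicate 1, S724A replicate 1 or S724A replicate 2 (adjusted p up to 0.104). Col6a1 at -0.59 ± 0.15 was lost without EGFP replicate 1, EGFP replicate 2 or any 1 of the 3 S724A arrays (adjusted p up to 0.166). Of 17 cytosolic heat shock genes 2 fell, Hspa1a and Hspa1b (3 adjusted over the list alone). Their list had adjusted p = 0.00225, but adjusted p = 0.302 with an estimated correlation. Among 20 NRF2 and antioxidant genes 3 fell (3 adjusted over the list alone): Taldo1 at -1.45 ± 0.21, Txnrd1 at -0.83 ± 0.12 and Abcc4 at -1.02 ± 0.24. The last was lost without EGFP replicate 3, S724A replicate 1 or S724A replicate 2 (adjusted p up to 0.0931). The NRF2 shift (adjusted p = 0.00980, but adjusted p = 0.580 with an estimated correlation) was lost without EGFP replicate 3 (adjusted p = 0.0818).

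NF-kB and chemokine genes lay higher by a mean of 0.69 with S724A IRE1a (adjusted p = 0.00402, but adjusted p = 0.580 with an estimated correlation). Without S724A replicate 3 this shift was lost (adjusted p = 0.214). Of these 23 genes 4 rose (6 adjusted over the list alone): Cxcl2, Cxcl1 by 1.82 ± 0.51, Ccl2 by 1.63 ± 0.40 and Sod2 by 0.57 ± 0.12. The calls of Cxcl1 and Ccl2 were lost without any 1 of the 3 EGFP arrays, S724A replicate 2 or S724A replicate 3 and in 7 and 2 other settings (adjusted p up to 0.172 and 0.106). That of Sod2 was lost without EGFP replicate 2 and with the mean of its probe sets (adjusted p up to 0.0522). Acute phase genes had a mean of 0.42 (adjusted p = 0.00980, but adjusted p = 0.389 with an estimated correlation). The acute phase shift was lost without S724A replicate 3 and with the stricter filter (adjusted p up to 0.107). Of these 25 genes Itih4 changed by -1.31 ± 0.18 and Saa3 by 2.54 ± 0.66 (1 and 1 also adjusted over the list alone). The call of Saa3 was lost without any 1 of the 3 EGFP arrays, from the 6 arrays alone and with trended variances (adjusted p up to 0.152).

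Phospholipid synthesis genes had a mean change of 0.26 with S724A IRE1a (adjusted p = 0.00980, but adjusted p = 0.423 with an estimated correlation). That shift was lost after quantile normalisation and with the stricter filter (adjusted p up to 0.0848). Of these 17 genes 2 rose (2 adjusted over the list alone): Lpin3, a phosphatidate phosphatase gene, by 1.52 ± 0.29, and Lpin2 by 0.54 ± 0.11. The call of Lpin2 was lost without EGFP replicate 2 or S724A replicate 3 (adjusted p up to 0.0592). Cholesterol synthesis genes had a mean of 0.18 (adjusted p = 0.0275, but adjusted p = 0.302 with an estimated correlation). The cholesterol shift was lost without S724A replicate 3, after quantile normalisation and with the stricter filter (adjusted p up to 0.176). Of these 20 genes 3 rose (4 rose and 1 fell adjusted over the list alone): Dhcr7 by 0.87 ± 0.16, Ebp by 0.62 ± 0.14 and Msmo1 by 0.49 ± 0.13. The call of Ebp was lost without EGFP replicate 1, EGFP replicate 2, S724A replicate 2 or S724A replicate 3 (adjusted p up to 0.0987). That of Msmo1 was lost without any 1 of the 6 arrays and in 4 other settings (adjusted p up to 0.180). Lymphocyte and neutrophil markers had a mean of -0.21 (adjusted p = 0.0288, but adjusted p = 0.423 with an estimated correlation). The marker shift was lost without EGFP replicate 2, after quantile normalisation and with no filter (adjusted p up to 0.155). Of these 10 markers 1 fell (3 adjusted over the list alone): Ltf by 0.48 ± 0.09. The means of the markers of macrophages, endothelial cells, stellate cells, cholangiocytes and erythroid cells were also negative, at -0.12, -0.17, -0.11, -0.31 and -0.18, without a shift (adjusted p = 0.25, 0.0578, 0.141, 0.163 and 0.152). With the replicate number as a block within each arm the endothelial and cholangiocyte markers passed (adjusted p = 0.0486 and 0.0457).

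Gluconeogenesis genes did not shift with S724A IRE1a (adjusted p = 0.402), and limma placed 0 of 15 past the threshold. G6pc, Pck1, Tat, Ppargc1a and Fgf21 differed by 0.09 ± 1.07, 0.63 ± 0.22, 0.78 ± 0.27, -0.40 ± 0.32 and 0.70 ± 0.51 (adjusted p = 0.968, 0.110, 0.10, 0.469 and 0.419). With the block within each arm Pck1, Tat and Fgf21 passed (adjusted p = 0.0326, 0.00107 and 0.0367). With the block over all arrays Pck1 and Tat passed (adjusted p = 0.0494 and 0.0286), and Tat also passed without EGFP replicate 1 (adjusted p = 0.0359).

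In total 631 genes rose and 366 fell with S724A IRE1a, 123 and 70 of them by at least 2-fold. The groups did not overlap in 5436 genes (33.4%), against 10% by chance if the arrays were independent, which same-number arrays were not. Of 36 lists, 8 shifted up and 4 down, and 3 held with an estimated correlation. With the replicate number as a block within each arm 2347 genes passed, which included the 997 unblocked ones, and 18 lists shifted in camera, 11 up and 7 down. Cell cycle, fatty acid oxidation and FOXO genes were then higher (adjusted p = 0.0124, 0.0272 and 0.0498) and xenobiotic metabolism genes lower (adjusted p = 0.0379). Without EGFP replicate 2, EGFP replicate 3, S724A replicate 2 or S724A replicate 3 the counts were 485, 642, 538 and 596, of which 296, 398, 360 and 407 rose. The share of rising genes, 63.3%, was 48.3% after quantile normalisation and 45.8% after median centring.

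The wild-type and S724A effects ran together. Of the genes that rose, 500 rose with both viruses, against 32.1 for independent draws, and of those that fell, 226 fell with both, against 9.48. Both comparisons share the EGFP arrays, so independent draws understate the overlap expected without an effect, and that overlap was not simulated. Without EGFP replicate 2 the first count was 254, and without S724A replicate 2 the counts were 318 and 147. In 0 cases did a gene pass limma's threshold in opposite directions. Across the 16294 genes, which are not independent replicates, the effects correlated with r = 0.840 and rho = 0.776. Because both share the EGFP arrays, unchanged groups would give a simulated r of 0.50 (highest 0.531) if arrays were independent, and the covariance was 0.0957 against a simulated 0.0149. Arrays of the same number were not independent. Residuals of the same-number arrays, which keep that pairing, gave r = 0.653, 0.603 and 0.384 in the 3 experiments. The effects themselves had r = 0.719, 0.857 and 0.709 by experiment.

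**Figure D3:**
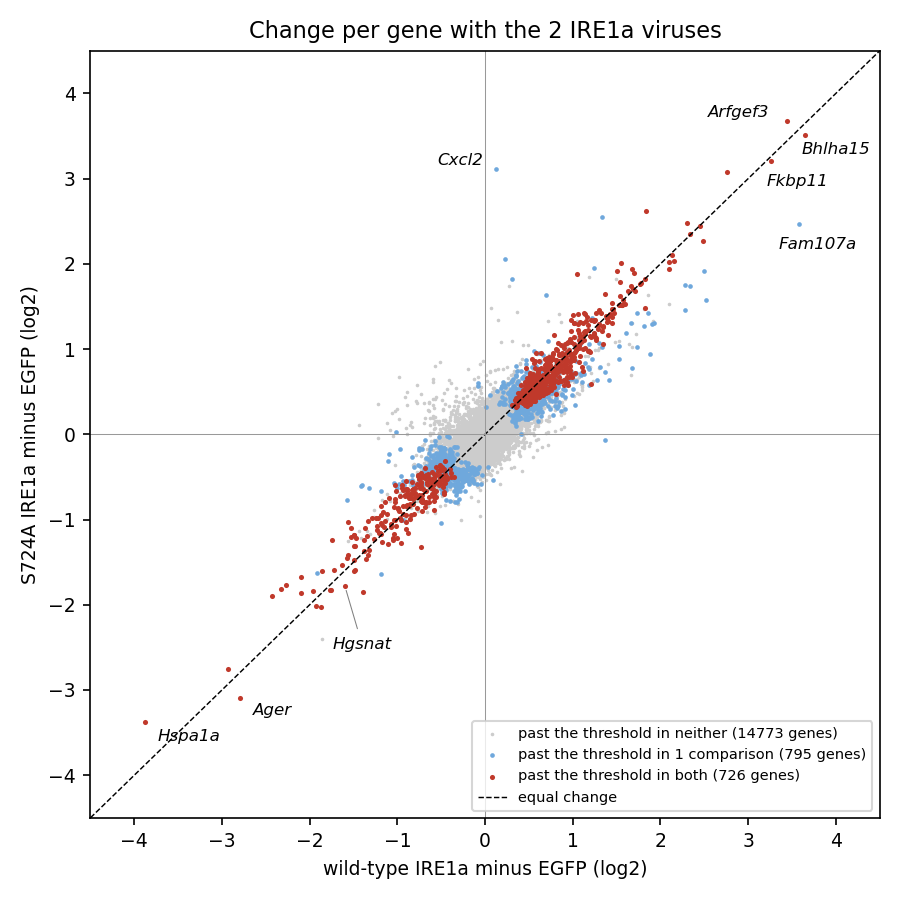
Change of each tested gene (dots) with wild-type IRE1a (horizontal axis, log2) against its change with S724A IRE1a (vertical axis, log2), coloured by whether it passed the threshold in neither comparison, 1 or both; the dashed line marks equal change. Genes past the threshold in both lie along the line, from Hspa1a at -3.88 and -3.37 to Bhlha15 at 3.65 and 3.51, and both changes share the EGFP arrays.

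Wild-type and S724A IRE1a were compared directly to ask what the replaced serine alters. The list with the smallest camera p was the ER chaperones, with a mean difference of -0.26 and 21 of 26 members below 0, that is, lower with wild-type (adjusted p = 1.26e-11, but adjusted p = 0.420 with an estimated correlation). No chaperone passed over all genes, and 6 were lower adjusted over the list alone. Creld2 differed by -0.84 ± 0.15, Pdia3, a disulfide isomerase, by -0.67 ± 0.15, Pdia6 by -0.46 ± 0.12 and Dnajc3 by -0.46 ± 0.11 (adjusted p = 0.203, 0.622, 0.705 and 0.705). The other of the 2 probe sets of Pdia6 had the opposite order: against EGFP it changed by 0.42 with wild-type and 0.17 with S724A. Translocation and COPII genes had a mean difference of -0.00265 ± 0.0584 (SE over 3 experiments) and did not shift (adjusted p = 0.549).

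NF-kB and chemokine genes had a mean difference of -0.66 between wild-type and S724A IRE1a (camera adjusted p = 3.21e-08, but adjusted p = 0.420 with an estimated correlation). By experiment the difference was -0.15, -0.44 and -1.39, and without S724A replicate 3 the mean was -0.26 (adjusted p = 0.0201). Of these 23 genes limma placed 0 past the threshold, and 0 adjusted over the list alone. Cxcl2 differed by -2.99 ± 0.87 (adjusted p = 0.801), with S724A arrays at 10.85 ± 1.92 (SD). N-glycosylation, ER-associated degradation and cholesterol synthesis genes had mean differences of -0.13, -0.12 and -0.12, and endothelial markers of 0.17. Camera gave these 4 lists adjusted p = 6.82e-06, 0.00104, 0.0497 and 0.0191, but adjusted p = 0.558, 0.420, 0.420 and 0.420 with an estimated correlation. In each limma placed 0 members past the threshold, over all genes or adjusted over the list alone. The cholesterol shift was lost without wild-type replicate 2, wild-type replicate 3 or S724A replicate 3 and in 5 other settings, and the endothelial shift without wild-type replicate 1 (adjusted p up to 0.181 and 0.115). Gene by gene the smallest p-values belonged to Slc39a6, a zinc transporter gene, at -0.86 ± 0.12, and to the defensin gene Defb1 at 1.44 ± 0.23 (adjusted p = 0.109 and 0.165). After these came Sgk1 at 0.62 ± 0.10, Arih1 at -0.61 ± 0.11, Rxylt1 at -0.80 ± 0.15, Ly6g2 at 0.60 ± 0.11 and Cxcl17 at 0.69 ± 0.14 (adjusted p = 0.165, 0.20, 0.20, 0.20 and 0.323). Xbp1, Dnajb9 and Ern1 differed by 0.11 ± 0.11, 0.07 ± 0.20 and -0.34 ± 0.19 (adjusted p = 0.925, 0.983 and 0.856).

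At the threshold 0 of 16294 genes differed between wild-type and S724A IRE1a in limma, while 997 had an unadjusted p under 0.05, against 814.7 expected by chance. Array weights gave 32 genes. Trended and robust variances gave 2, Slc39a6 and Sgk1 (0.62 ± 0.09, adjusted p = 0.0349). With the replicate number as a block within each arm 2 passed, both lower with wild-type: Slc39a6 (adjusted p = 0.0111) and Fam171b (-1.13 ± 0.13, adjusted p = 0.0155). Fam171b was named after its values were seen. For 96.7% of genes the 95% confidence interval of the difference lay within 2-fold. Of 36 lists, 1 shifted up and 5 down and 0 held with an estimated correlation. The count of lists was 10, 10 and 11 without wild-type replicate 1, S724A replicate 2 and S724A replicate 3. With the replicate number as a block within each arm 11 lists shifted in camera, 3 up and 8 down. Fatty acid oxidation and interferon genes were then higher with wild-type (adjusted p = 0.00109 and 0.0206). Plasma protein, acute phase and NRF2 genes were lower (adjusted p = 0.0276, 0.0332 and 0.0347).

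The hairpin against IRE1a was compared with the control hairpin, both with glucagon, to show which genes depend on IRE1a in hepatocytes given that hormone. Ern1 itself fell by 1.47 ± 0.19 (adjusted p = 0.00293), to 36.2% of the control, from 8.98 ± 0.11 to 7.52 ± 0.08 (SD), by its brightest probe set, 1437119_at. With the mean of its probe sets the change was -0.56. Its 4 dimmer probe sets did not pass (adjusted p = 0.148, 0.211, 0.411 and 0.633). Of these, 3 differed by -0.58 ± 0.14, -0.65 ± 0.17 and -0.43 ± 0.14, and the dimmest by 0.35 ± 0.17. With 3 arrays against 3, an exact two-sided permutation test of Ern1 gave p = 0.1, the smallest it can give. In the model of 5 groups none of the 5 probe sets passed with either IRE1a virus, and the brightest was higher by 0.12 ± 0.19 with wild-type and 0.46 ± 0.19 with S724A. The IRE1a sequence of these viruses is not given in the sources used here, so it is unknown whether the probe sets detect it.

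Other genes past the threshold with the hairpin were few. Mob1a, a Hippo pathway kinase activator gene, fell by 1.22 ± 0.08 (adjusted p = 6.32e-06), and Dntt, a DNA polymerase gene, rose by 1.32 ± 0.11 (adjusted p = 0.000105). Dctd, deoxycytidylate deaminase, changed by -1.19 ± 0.15, the transcription factor gene Tfcp2l1 by -1.18 ± 0.16, Mal2, a membrane trafficking gene, by -1.39 ± 0.21 and Bche, butyrylcholinesterase, by 0.77 ± 0.09. These 4 calls were lost when the 6 arrays were fitted alone, that of Tfcp2l1 also with the mean of its probe sets and that of Mal2 also without IRE1a-hairpin replicate 1 (adjusted p up to 0.120, 0.244, 0.120 and 0.131). Hmga2-ps1 changed by -1.24 ± 0.23, Alpl by 1.04 ± 0.20, Pcdh9 by 0.82 ± 0.15, Slc22a5 by 0.78 ± 0.13 and Aspa by 0.69 ± 0.13. All 5 calls were lost from the 6 arrays alone and without control-hairpin replicate 1, IRE1a-hairpin replicate 2 or IRE1a-hairpin replicate 3 (adjusted p up to 0.206, 0.480, 0.327, 0.120 and 0.449), and all but that of Slc22a5 in 2 to 4 other settings. All but that of Pcdh9 were also lost without IRE1a-hairpin replicate 1, those of Hmga2-ps1, Pcdh9 and Slc22a5 without control-hairpin replicate 2, and those of Hmga2-ps1, Pcdh9 and Aspa without control-hairpin replicate 3.

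Gluconeogenesis genes did not shift with the hairpin (adjusted p = 0.539), and limma placed 0 of 15 past the threshold. Pck1, G6pc, Ppargc1a and Tat differed by -0.06 ± 0.22, -0.36 ± 1.07, 0.08 ± 0.32 and -0.10 ± 0.27 (adjusted p = 0.961, 0.952, 0.968 and 0.944). The error of G6pc is pooled over all 5 groups, and its signal in arrays without glucagon ranged from 7.83 to 12.23. It was 11.26, 11.44 and 11.32 with the control hairpin, and 11.24, 11.05 and 10.65 with the hairpin against IRE1a. That pooled test therefore cannot decide on a fall of G6pc of this size. G6pc passed in no alternative, the 6 arrays alone included (lowest adjusted p = 0.55 in limma). The cAMP and CREB target genes had a mean difference of -0.02 (adjusted p = 0.539), and limma placed 0 of 22 past the threshold. Xbp1, Hspa5, Dnajb9, Ddit3 and Atf4 differed by -0.08 ± 0.11, -0.04 ± 0.11, 0.15 ± 0.20, -0.31 ± 0.19 and 0.07 ± 0.12 (adjusted p = 0.881, 0.941, 0.875, 0.722 and 0.910).

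**Figure D4:**
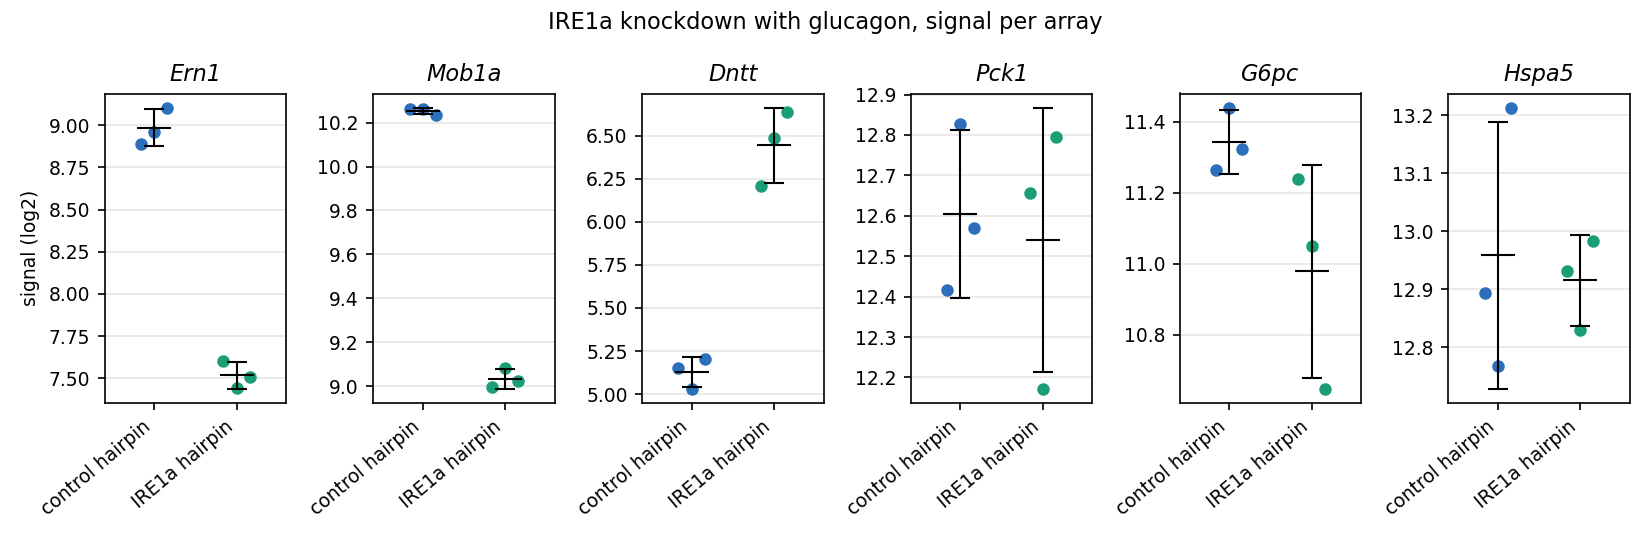
Signal per array (log2, vertical axes that differ between panels and do not start at 0) of 6 named genes with the control hairpin and the hairpin against IRE1a, both with glucagon; dots are arrays, horizontal bars are means and whiskers are SDs (n = 3). Ern1 and Mob1a lie lower and Dntt higher in all 3 arrays with the hairpin against IRE1a. Pck1 and Hspa5 overlap, and G6pc lies lower in all 3 arrays but did not pass the test.

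Cell cycle genes had a mean difference of 0.37 with the hairpin against IRE1a, with 26 of 28 above 0 (camera adjusted p = 0.000427, but adjusted p = 0.752 with an estimated correlation). Without control-hairpin replicate 1 this shift was lost (adjusted p = 0.0737). Limma placed 0 of these genes past the threshold, and 0 adjusted over the list alone. ER chaperones, N-glycosylation and cholesterol synthesis genes had mean differences of -0.11, -0.12 and -0.12. Camera gave these 3 lists adjusted p = 0.00854, 0.00554 and 0.00554, but adjusted p = 0.752, 0.752 and 0.638 with an estimated correlation. In limma 0 members passed over all genes, and 0, 1 and 2 were lower adjusted over the list alone: Magt1 at -0.58 ± 0.13, Hsd17b7 at -0.44 ± 0.11 and Msmo1 at -0.53 ± 0.13 (adjusted p = 0.111, 0.174 and 0.184 over all genes). The chaperone and N-glycosylation shifts were lost without control-hairpin replicate 1 or IRE1a-hairpin replicate 2, the former also in 2 other settings, and the cholesterol shift without IRE1a-hairpin replicate 3 (adjusted p up to 0.164, 0.128 and 0.0572). Ribosomal protein genes had a mean of -0.08 (adjusted p = 0.0136, but adjusted p = 0.836 with an estimated correlation). The ribosomal shift was lost without control-hairpin replicate 2, control-hairpin replicate 3 or IRE1a-hairpin replicate 1 and with the stricter filter (adjusted p up to 0.185). Of these 23 genes 1 fell (1 adjusted over the list alone): Rpl14 by 0.59 ± 0.11. Its call was lost in 5 settings and without any 1 of the 6 arrays except control-hairpin replicate 1 (adjusted p up to 0.396). Markers of macrophages, endothelial cells, stellate cells, lymphocytes and neutrophils, and erythroid cells had means of 0.14, 0.12, 0.06, 0.14 and 0.16, and cholangiocyte markers of -0.15, without a shift in camera (adjusted p = 0.0958, 0.20, 0.432, 0.0935, 0.0958 and 0.715). Of the macrophage markers 13 of 14 lay above 0, and of the endothelial markers 13 of 16.

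In total 8 genes rose and 30 fell with the hairpin against IRE1a, 2 and 10 of them by at least 2-fold, and 1260 had an unadjusted p under 0.05. The groups did not overlap in 1881 genes (11.5%), against 10% by chance for independent arrays. Same-number arrays were not independent, so the chance share here is not known. The count of 38 became 200 (87 rose and 113 fell) with the replicate number as a block within each arm, 64 with it as a block over all arrays and 78 with array weights. The 6 arrays alone gave 5: Ern1, Mob1a, Dntt, and Cap1 and 9530068E07Rik, named after their values were seen (-1.06 ± 0.11 and -1.15 ± 0.10). Leaving out control-hairpin replicates 1, 2 and 3 gave 23, 19 and 75 genes, and leaving out IRE1a-hairpin replicates 1, 2 and 3 gave 17, 13 and 22. The excess of falls did not hold without control-hairpin replicate 3, where 37 rose and 38 fell. Of 36 lists, 1 shifted up and 4 down and 0 held with an estimated correlation. The count of lists was 9 without control-hairpin replicate 3 or IRE1a-hairpin replicate 2.

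The effects of the IRE1a viruses and of the hairpin were set side by side to ask whether the same genes move in opposite directions. These arrays showed a lower Ern1 signal with the hairpin, while in the model of 5 groups no Ern1 probe set passed the threshold with the viruses. Across the 16294 genes, which are not independent replicates, the wild-type and hairpin effects had r = -0.12 and rho = -0.15. Relabelling the arrays within each arm gave values as large in a permutation p of 0.3 (2 such relations were tested, Benjamini-Hochberg adjusted p = 0.3). The S724A and hairpin effects had r = -0.22 and rho = -0.29 (permutation p = 0.08, adjusted p = 0.16). These relabellings ignore the pairing of same-number arrays. Swaps within the pairs gave an exact permutation p of 0.31 and 0.19 (adjusted p = 0.31 for both), where 0.0625 is the smallest they can give. By experiment number, which the labels tie across the arms nowhere, the wild-type relation had r = -0.01, -0.16 and -0.02, and without IRE1a-hairpin replicate 2 it had r = -0.04. Of the 828 genes that rose with wild-type IRE1a, 511 were lower with the hairpin and 317 higher, while of the 422 that fell, 225 were also lower and 197 higher. Named after their values were seen, Dntt and Pcdh9 fell with wild-type IRE1a (at -0.99 and -0.71) and rose with the hairpin (by 1.32 and 0.82). Rbbp9 and Smim7 did the reverse, and Lrp11 and Zdhhc16 fell in both. The hairpin call of Pcdh9 was lost in 5 settings and without any 1 of the 6 arrays except IRE1a-hairpin replicate 1 (adjusted p up to 0.327). Those of Rbbp9, Smim7, Lrp11 and Zdhhc16 were lost from the 6 arrays alone and without control-hairpin replicate 2, IRE1a-hairpin replicate 1 or IRE1a-hairpin replicate 2, and all but that of Smim7 also without control-hairpin replicate 1 (adjusted p up to 0.396, 0.315, 0.191 and 0.272). Smim7 was also lost with wild-type IRE1a without EGFP replicate 1, EGFP replicate 2 or wild-type replicate 3 and with the mean of its probe sets (adjusted p up to 0.149).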

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

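All tests of explanations in this part were chosen after the results they address were seen, while the counts over other splits of the arrays were planned.

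Probe sets without a single gene name, 7157 of which were tested, lay outside the comparisons of named genes but carried signal in each of them: 78 passed limma's threshold with wild-type IRE1a, 87 with S724A IRE1a, 1 between the 2 proteins and 6 with the hairpin against IRE1a. The 1 probe set that parted the proteins, 1427585_at, had a mean signal of 6.30 ± 1.61 (SD, n = 3) in the S724A arrays, between 4.60 and 7.80, against values between 2.30 and 3.38 in the 12 other arrays.

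The first pattern is the 226 genes that fell with both IRE1a viruses (147 without S724A replicate 2). If they fell because the EGFP arrays stand apart from every other group, the control-hairpin arrays should resemble the IRE1a arrays for these genes. Their median place between EGFP (0) and the IRE1a groups (1) was 0.0802 (95% interval of the median from -0.0419 to 0.177). That interval is taken over genes, which are not independent replicates, and leaves out the spread of the arrays. The place argues against that reading for the pattern as a whole, although the hairpin arrays differ in time and glucagon too. The reading stays open for the 62 genes (27.4%) with a place of 0.5 or more, among them Rgcc (1.73), Cyp2e1 (0.920), Plod2 (0.523) and Hspa1a, Hspa1b and Ager (by 1 of its 2 probe sets), whose lowest place was 0.944, so these falls may reflect a high level in the EGFP arrays. For the 500 genes that rose with both viruses the median place was 0.324, and 175 (35%) had a place of 0.5 or more. It stays open for these rises as well. Decay of messages by the IRE1 RNase stays open too: 3 of the 15 reported substrates, Hgsnat, Tapbp and Cyp2e1, fell with both viruses against 1.39% of all genes (Fisher's exact test, one-sided, p = 0.00106), but Hgsnat alone was left without EGFP replicate 1 or without S724A replicate 2 (p = 0.150 and 0.127 in that exact test). That exact test treats genes as independent draws and counts Cyp2e1, whose fall may reflect a high level in the EGFP arrays. The other 223 genes are outside that list, and no test here tells direct decay from changes in transcription.

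The second pattern is the lower level of ER chaperones with wild-type than with S724A IRE1a, a mean difference of -0.26 (95% interval over the 3 experiments from -0.54 to 0.03). Wild-type replicate 3 had the lowest correlation with its group, yet without it the difference was -0.32, and without S724A replicate 3 it was -0.26, so neither array accounts for it. A weaker overall output of the wild-type virus would predict a difference of -0.20 in translocation and COPII genes. Their mean of -0.00265 ± 0.0584 (SE, n = 3 experiments) has a 95% interval from -0.25 to 0.25, so they cannot tell it apart. N-glycosylation and ER-associated degradation genes were lower with wild-type by 17.5% and 17.0% of their S724A rise, near the 21.9% of the chaperones. These shares go with a weaker output, but the 95% intervals of the differences, -0.46 to 0.20 and -0.31 to 0.08, span both signs. The translocation and COPII share was 0.28%. Over genes past the threshold in the same direction with both viruses, the ratio of wild-type to S724A change had a median of 1.03 (quartiles 0.92 and 1.18). That argues against a weaker output across these genes, though both changes share the EGFP arrays. An effect of the replaced serine on a subset of the response may remain as a hypothesis; the shift was lost when the correlation between genes was estimated (adjusted p = 0.420), and a difference in IRE1a protein between the viruses was not tested.

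The third pattern is the genes other than Ern1 that changed with the hairpin against IRE1a. If they follow the level of IRE1a in both arms, they should move the opposite way with wild-type IRE1a: 26 of 37 had the opposite sign (70.3%, against 56.0% of all genes) and the median change against the hairpin's direction was 0.14, while 4 passed in the opposite direction (10.8%, exact 95% interval from 3.03% to 25.4%) and 2 in the same. The exact interval treats these genes as independent and leaves out the spread of the arrays. The median of 0.14 was smaller than the median size with the hairpin, 0.78, which was taken over genes chosen for passing. The counts cannot decide on opposite changes of that size, since none was simulated. With wild-type IRE1a 79.2% of simulated changes of 1 and 24.7% of changes of 0.5 were recovered. Smaller opposite changes stay open too, and the 2 arms differ in time and glucagon. A lower signal across the knockdown arrays cannot be told apart either, because the authors' quantile normalisation holds the median change of all genes, 0.0206, near 0. Effects of this hairpin on messages other than Ern1 could not be tested, since only 1 hairpin was used and its sequence is not given in the sources used here.

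The 6 arrays of a comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05. With wild-type IRE1a 1 of 10 splits, the real one, gave as many genes as the 1250 found, and the highest other split gave 0; with S724A IRE1a 1 of 10 gave as many as 997, and the highest other gave 0. Between wild-type and S724A the real split gave 0, so all 10 gave as many, and the highest other gave 15. With the hairpin 2 of 10 gave as many as 38, and the other gave 68; that split parts 1 of the 3 same-number pairs, while among splits that part all 3 pairs the highest other gave 0 in each comparison. The replicate number is thus a structure of these samples, and with it as a block within each arm 200 genes passed with the hairpin.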

How the results depend on the processing

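The replicate block within each arm was added after the data were seen, while the other alternatives were planned. Of the named genes past the threshold, 54 of 73 with wild-type IRE1a, 44 of 59 with S724A and 3 of 13 with the hairpin (Ern1, Mob1a and Dntt) were past it in all alternatives; of those lost, 11 of 19, 6 of 15 and 0 of 10 were lost only when an array was left out. Of the named genes not past the threshold, 10 of 17, 16 of 21 and 4 of 29 passed in some alternative, and 10 of 42 between wild-type and S724A. Directions of the named genes past the threshold held in these alternatives, although among cases with several probe sets all had the same sign in 68 of 79. With the mean of a gene's probe sets 14 of 73, 11 of 59 and 3 of 13 of these changes shrank by more than 1.5 times. In the alternative of each probe set on its own, a named gene was scored by its brightest probe set alone. The counts past the threshold in all alternatives thus do not show that a gene's other probe sets passed: the 4 dimmer ones of Ern1 did not.

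Where a count moved by more than 1.5 times, the cause was not tested unless stated. Array weights gave 2522 genes with wild-type IRE1a, 3169 with S724A, 32 between the 2 and 78 with the hairpin. The replicate block over all arrays gave 1510 genes with S724A and 64 with the hairpin; the block within each arm, which removes the spread shared by arrays of the same number, gave 2539, 2347, 2 and 200. Trended and robust variances gave 2 between wild-type and S724A. The 6 arrays alone, with fewer arrays to estimate the spread, gave 5 genes with the hairpin. An estimated correlation between genes left 2, 3, 0 and 0 lists. Between wild-type and S724A, quantile normalisation gave 10 lists, the 6 arrays alone 11 and the block within each arm 11; with the hairpin the latter 2 each gave 9. For Ern1 with the hairpin, its other probe sets gave -0.58, -0.65, -0.43 and, reversed, 0.35; the last had the lowest signal, 3.66 ± 0.01 with the control hairpin.

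Leaving out 1 array gave between 715 (without EGFP replicate 2) and 1108 genes with wild-type IRE1a and 9 to 12 lists. With S724A it gave 485 (without EGFP replicate 2) to 979 genes, with 642, 538 and 596 without EGFP replicate 3, S724A replicate 2 and S724A replicate 3, and 10 to 14 lists. Between the 2 it gave 0 to 0 genes in limma, where 997 had an unadjusted p under 0.05, and 5 to 11 lists (10, 10 and 11 without wild-type replicate 1, S724A replicate 2 and S724A replicate 3). With the hairpin it gave 13 to 75 genes (23, 19 and 75 without control-hairpin replicates 1, 2 and 3; 17, 13 and 22 without IRE1a-hairpin replicates 1, 2 and 3) and 4 to 9 lists, 9 without control-hairpin replicate 3 or IRE1a-hairpin replicate 2. The wild-type and S724A effects had r between 0.794 and 0.856, and the wild-type and hairpin effects between -0.14 and -0.04 (the latter without IRE1a-hairpin replicate 2). Signals near background limit the dim genes: the probe set of Pck1 in the 48-hour arrays averaged 5.36 with EGFP.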

Other observations

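The gene families in this part were chosen after their values were seen, and no test of an explanation is reported for them. Carboxylesterase genes, which encode enzymes that hydrolyse esters of drugs and lipids, were lower with both IRE1a viruses: of 12 tested, 4 fell with wild-type and 4 with S724A IRE1a, namely Ces1c, Ces1f, Ces1g and Ces2a. Ces1g changed by -1.96 ± 0.31 with wild-type and -1.83 ± 0.31 with S724A, and Ces1f by -1.49 ± 0.32 and -1.48 ± 0.32. The family means were -0.88 and -0.82, and stayed between -0.97 and -0.82 after quantile normalisation or median centring. Over 260 symbol families, camera gave that shift adjusted p = 4.41e-05 and 0.000899, but adjusted p = 0.961 and 0.835 with an estimated correlation.

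Of 76 genes of mitochondrial ribosomal proteins tested, 14 rose with wild-type IRE1a, and 9 rose and 1 fell with S724A; after quantile normalisation 13 rose and 1 fell, and 4 rose and 1 fell, and after median centring 6 rose, and 3 rose and 1 fell. The means of the family were 0.19 in both comparisons, and 0.10 to 0.12 under those scalings. Among the same symbol families, camera gave the large-subunit genes (Mrpl) adjusted p = 0.000480 and 8.05e-05 and the small-subunit genes (Mrps) adjusted p = 0.00399 and 0.000899, but adjusted p = 0.961 and 0.835 with an estimated correlation for either. Mrps12 rose by 0.86 ± 0.11 with wild-type and 0.79 ± 0.11 with S724A.

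G6pc varied by experiment more than by virus. Replicate 1 had signals of 11.15, 12.23 and 11.85 with EGFP, wild-type and S724A IRE1a, replicate 2 had 7.83, 8.56 and 8.37, and replicate 3 had 8.81, 8.68 and 7.84. With glucagon all 6 arrays lay between 10.65 and 11.44. In S724A replicate 3, Cxcl2, Cxcl1, Saa3 and Ccl2 reached 12.83, 13.70, 13.59 and 13.40, above every other array.

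Wild-type replicate 3 had a 3'-to-5' difference of the Actb control probe sets of 1.00 on the log2 scale, against 0.38 to 0.61 in the 14 other arrays, and a mean correlation with its own group of 0.983, against 0.989 to 0.995. Its Actb signal was 13.26, against 13.99 to 14.38. For the Gapdh and Tfrc control probe sets its 3'-to-5' difference was 0.16 and 2.11. Control-hairpin replicate 3 and IRE1a-hairpin replicate 1 had higher values, 0.23 for Gapdh and 2.19 for Tfrc. The sex-linked transcripts Xist and Eif2s3y lay between 6.09 and 6.71 and between 9.40 and 10.36 in all 15 arrays, so they part no array from the others.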
